A study of Mus musculus with 7 samples.

How the data were processed

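RNA of single cells was counted in 7 mouse libraries made with the 10x Genomics 3' v2 kit. There were 4 of CD45-enriched whole trachea (no injury named in the title, and days 1, 4 and 7 after a dose of 15 microlitres of 2% polidocanol), and 3 of tracheal epithelium, tracheal mesenchyme and lung. The treatment protocol mentions a sham control given saline, but the labels of the whole-trachea library without an injury day do not say whether it had one. That library is therefore called no injury named. Each group held 1 library. The whole-trachea labels name an enrichment for CD45 with later processing to obtain myeloid cells, the epithelium label a sort on CD45, and the mesenchyme and lung labels a sort on CD45 and F4/80. The epithelium was released with dispase and trypsin and the other tissues with other enzymes. A depth of about 200 (in K reads per cell) is stated, and 329, 721 and 460 cells for epithelium, mesenchyme and lung, which are the numbers of barcodes found.

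Per the submitters' processing notes, Cell Ranger 3 and Seurat were used with mouse genome build GRCm38; their order and the annotation are not given. The UMI counts per gene and barcode were used as deposited by the authors, who had already called cells. They are whole numbers without normalization. The trachea libraries share one feature set and the tissue libraries another with older symbols, so the injury and the tissue libraries were clustered apart and never compared with each other. At most 1 barcode was shared between any pair of libraries clustered together. The tissue libraries hold an added reporter sequence, tdTomato, with 0 UMIs in each, which allows up to 3.33, 0.660 and 1.43 CPM in epithelium, mesenchyme and lung.

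Barcodes with at least 200 genes and at most 10% mitochondrial UMIs were kept: 440, 1555, 1415 and 1646 with no injury named and on days 1, 4 and 7, and 325, 721 and 449 in epithelium, mesenchyme and lung. This left out 251 whole-trachea and 15 tissue barcodes. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 0.8 followed, without integration of libraries. Ribosomal, mitochondrial, immunoglobulin, T cell receptor, haemoglobin and sex-linked genes were not used for clustering. Scrublet called 18 doublets (0.356%) in the whole-trachea libraries, so it has not worked there, and 14 (0.936%) in the tissue libraries; called doublets were kept. Each cluster took the class, of 24, whose fixed markers had the highest mean of scaled log expression, where that mean was at least 1 and at least 3 markers were found in at least 10% of cells. Other clusters stayed unnamed, and the minimum score was set after the data were seen.

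Injury comparisons used the pool of monocyte-like and macrophage-like cells, and tissue comparisons macrophage-like cells, alveolar macrophage-like cells left out of both. A class passed for comparison on its own where no cluster in it was led by more markers of another class than of its own. Macrophage-like cells failed this through cluster 5 of the whole-trachea libraries and cluster 11 of the tissue libraries. Their planned values, over all macrophage-like cells of a tissue or in macrophage-like cells alone, are still printed and carry that limit. Clusters 0 and 5 are therefore also compared by number, as are clusters 0, 11, 15 and 12 of the tissue libraries. The 2 clusterings number their clusters separately. Genes that lead a cluster are not reported as differences of that cluster. At least 20 cells were asked for on each side of a comparison, but against lung only 3, so those values rest on few cells. Monocyte-like cells alone, with 6 cells in the library with no injury named, were not compared.

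UMIs were summed over the cells of a class in each library and given as CPM, that is scaled to a common total, with exact Poisson 95% intervals. Ratios carry exact conditional (Clopper-Pearson) 95% intervals, and shares of cells exact binomial 95% intervals. With 1 library per group there was no test, no p-value and no count of changed genes. Where a gene had 0 UMIs in a library, its ratio is a bound at a floor of 3 counts for the sum. A gene was named by a rule fixed before the data were examined, as were the lists, the pools, the cell filter and most of the alternatives. The rule asked for at least 50 CPM in the higher library, at least 20 UMIs over both and a difference of at least 2-fold. Of the genes that passed, the 12 higher and the 8 lower ones whose interval bound nearest to 1 lay farthest from it were taken, together with the 2 most abundant members of each list. After the data were seen, the same rule was also run over genes found in at least 10% of the pool's cells in the higher library with at most 25% of their UMIs in 1 cell. Genes given within a numbered cluster, over all cells of a library or against lung alveolar macrophage-like cells, and Spp1 and Thbs1 where the rule did not name them, were chosen after their values were seen.

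Of the 20 gene lists, 15 covered classical monocyte, Lyve1-type macrophage, MHC class II, inflammatory cytokine and chemokine, alternative activation, growth factor, lipid-associated and matrix, interferon response, glycolysis and hypoxia, cholesterol and lipid handling, uptake of dead cells, chemokines for lymphocytes and eosinophils, proliferation, immediate early and dissociation, and tissue macrophage identity genes. The other 5, for RNA of other cells, covered neutrophil, epithelial, fibroblast, erythroid and lymphocyte genes. A list was summarised over members with at least 5 CPM in either library by the median log2 ratio with a 95% interval from 2000 Poisson draws. Beside it stand the number of members at least 2-fold higher or lower and the percentile of its median among 10000 random lists matched in size and expression over 20 bins. Levels in lymphocyte-like cells of the same library, which should lack macrophage genes, served as background. A level exceeds them where its 95% interval lies wholly above theirs, and other levels are not read as expression. In the whole-trachea libraries they include T cell-like cluster 17, whose second class was macrophage (score 0.71). Its median was 17779 UMIs, against 6875 in T cell-like cluster 3. If cluster 17 holds mixed cells the background is too high, so a level not above it does not show a lack of expression. In the tissue libraries lymphocyte-like cells include B cell-like cells, 29 in the epithelium and 38 in the lung, which express MHC class II, so they are no background for those genes. For shares of cells with a UMI, cells were also thinned to 5000 UMIs in the whole-trachea and 1500 in the tissue libraries, and shallower cells were left out.

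Alternatives were no cell filter, a stricter filter (500 genes, 5% mitochondrial UMIs), called doublets removed, Leiden resolutions of 0.4 and 1.5, and classes given per cell. Others were thinned cells, the mean of cells, scaling by the median of ratios, list members at 20 CPM or more, and macrophage-like cells alone. Alternatives added after the data were seen left out cells with over 1% epithelial list UMIs, the 5% of cells with the highest doublet scores, the highest cell of each gene or the Lyve1 cluster. Others added an unnamed cluster led by Retnla and Mmp12, used lung alveolar macrophage-like cells, or compared clusters by number.

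The steps were tested on simulated data, Poisson counts at the mean levels of each pair of pools with 200 genes changed by known folds. These counts held no variation between cells or libraries, so the rates and intervals that follow cover counting error only. They do not show how often the rule takes genes carried by few cells. In the real pools of days 1, 4 and 7, 7 of 20, 8 of 11 and 19 of 20 named genes had most of a library's UMIs in 1 cell. On days 1, 4 and 7 the rule took 98.5%, 93.5% and 100% of genes changed 3-fold, and 0 of 2407, 0 of 2364 and 0 of 2330 unchanged genes. For epithelium against mesenchyme it took 96.8% of genes changed 3-fold and 75 of 2355 unchanged genes, and for mesenchyme against 7 lung cells 68.9% and 1133 of 2387. Intervals held the true value for 95% to 98% of genes, and lists shifted by 2 on the log2 scale had medians from 1.93 to 2.02. Unshifted lists had medians from -0.095 to 0.061 at percentiles from 0.59 to 79.3, so an extreme percentile can arise without a shift and is not read alone. Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9 were used. No column of values of the 7 libraries went unused.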

Results

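Single-cell RNA-seq profiles of immune cells were collected from the airways and lungs of BL6J mice in 7 libraries. Of these, 4 came from whole tracheas enriched for CD45-positive cells: 1 whose title names no injury and 1 each from 1, 4 and 7 days after oropharyngeal delivery of 2% polidocanol, a detergent that strips the airway epithelium. The other 3 came from the epithelium peeled off uninjured tracheas, enriched for CD45, and from the remaining tracheal mesenchyme and whole lung, enriched for CD45 and F4/80. Every group was 1 library, so no difference had a replicate and none was tested, and every interval given covers counting error only. The whole-trachea libraries held 6534618 unique molecular identifiers (UMIs) in 458 barcodes with no injury named, 20839351 in 1625 on day 1, 19728240 in 1507 on day 4 and 22777235 in 1717 on day 7. The epithelium, mesenchyme and lung libraries held 900766, 4546836 and 2102158 UMIs in 329, 721 and 460 barcodes, the cell numbers that the protocol states. Median UMIs per barcode were 14098, 12141, 12598 and 12620 along the injury series, and 2133, 5363 and 3970 in epithelium, mesenchyme and lung.

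The injury series asks how tracheal macrophages and monocytes differ over the days after the epithelium is lost. Monocyte-like and macrophage-like cells, taken as 1 pool, made up 41.4% (36.7 to 46.1) of the cells with no injury named, 43.3% (40.8 to 45.8) on day 1, 39.8% (37.2 to 42.4) on day 4 and 38.8% (36.5 to 41.2) on day 7 (exact binomial 95% intervals). The CD45 sort sets which cells can appear in these shares. Neutrophil-like cells, the granulocytes that enter damaged tissue early, made up 0.455% (0.0551 to 1.63), 17.4% (15.5 to 19.3), 1.91% (1.26 to 2.76) and 2.85% (2.10 to 3.78) in the same order. Type 1 conventional dendritic cell-like cells, which present antigen to CD8 T cells, were 9.54% (6.97 to 12.7) with no injury named and 2.06% (1.41 to 2.89) on day 1, then 9.05% (7.60 to 10.7) and 7.35% (6.14 to 8.72). Alveolar macrophage-like cells numbered 34 on day 1 and 5 on day 4, and 0 in the other whole-trachea libraries. On day 1 most of the pool, 423 of 673 cells, sat in the monocyte-like cluster 13, which held 6 of 182 pool cells with no injury named. That cluster came almost wholly from day 1, so it cannot be told from a feature of that library. In the other 3 libraries cluster 0, led by Cx3cr1, and cluster 5, led by Lyve1, held most of the pool. They held 56 and 83 cells with no injury named, 243 and 238 on day 4, 222 and 274 on day 7. Macrophage-like cluster 7, led by Cd209f, held 16.5% (11.4 to 22.7) of the pool with no injury named. Its share was 2.675% (1.59 to 4.19) on day 1, 9.95% on day 4 and 13.3% on day 7. The 423 cells of cluster 13 also lower that day 1 share. Clusters left unnamed, by a threshold set after the data were seen, held 6.59%, 4.24%, 10.5% and 10.3% of the cells.

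**Figure D1:**
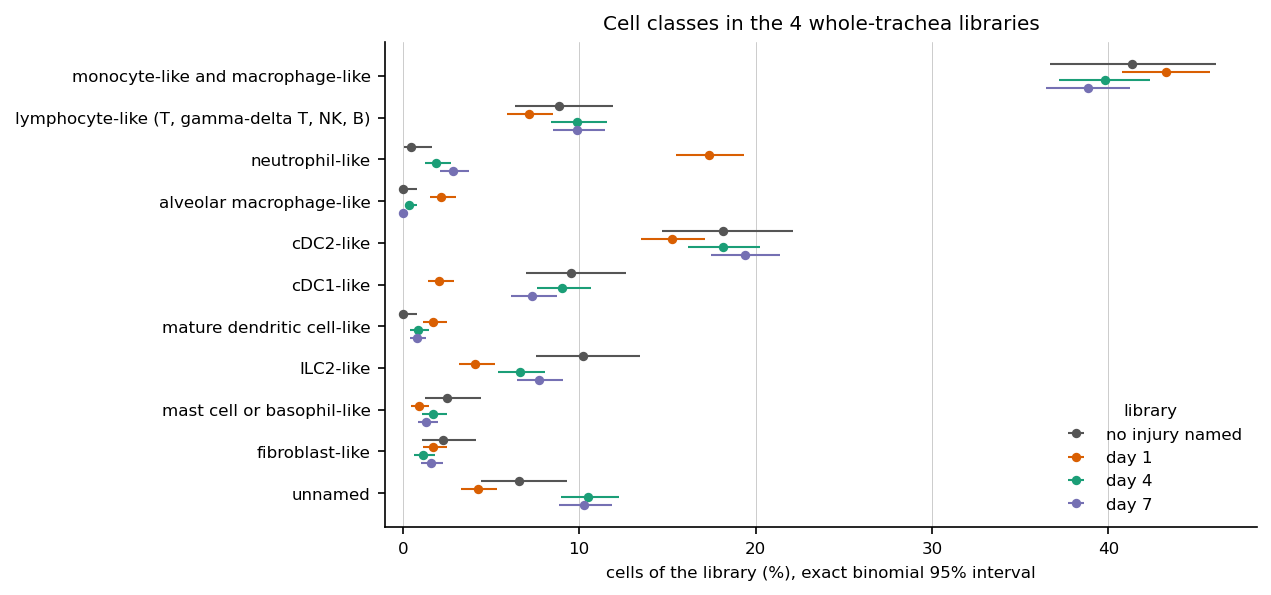
Share of the cells kept in each whole-trachea library (x axis, percent) for each cell class (y axis); points are shares and bars exact binomial 95% intervals. Neutrophil-like cells were 17.4% on day 1 and at most 2.85% in the other 3 libraries.

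Classical monocyte transcripts were higher in the day 1 pool. The classical monocyte list had a median log2 ratio of 3.52 (3.19 to 4.09), with 9 of 12 members at least 2-fold higher and 1 lower, at percentile 100 of 10000 random lists of like size and expression. Of its 12 members, 9 also served as markers of that class. Thbs1, the matrix protein thrombospondin 1, stood at 2056 (2029 to 2084) against 21.9 (16.6 to 28.2) CPM, 94.0-fold (72.9 to 124) higher. Fn1, which encodes fibronectin, was 68.4-fold (49.97 to 96.2) higher, and the matrix proteoglycan gene Vcan 103-fold (40.0 to 378) higher. Arg1, the arginase of wound macrophages, reached 490.5 (477 to 504) against 0.371 (0.00938 to 2.06) CPM, 5012 UMIs against 1 and a ratio of 1323-fold (237 to 52284). The neutrophil-attracting chemokine gene Cxcl3 was 346-fold (148 to 1066) higher, the activin subunit gene Inhba 359.9-fold (64.5 to 14226), and the EGF receptor ligand gene Areg 306-fold (54.8 to 12098). Also higher were the coagulation factor gene F10, 190.0-fold (52.5 to 1570), and the angiogenic factor gene Vegfa, 73.6-fold (38.7 to 161). Fabp5, a fatty acid binding protein gene, was 40.0-fold (32.4 to 49.98) higher, and the innate receptor genes Trem1 and Clec4e were 172-fold (30.7 to 6790) and 45.2-fold (29.5 to 73.1) higher. With no injury named, Thbs1, Cxcl3 and Vegfa had over 50% of their 59, 5 and 9 UMIs in 1 cell, and Arg1, Inhba, Areg and Trem1 had 1 UMI each, so the size of these ratios is uncertain. Beyond the 12 genes that the rule named, the cystine transporter gene Slc7a11 was 56.1-fold (28.4 to 130.3) higher.

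Several of these genes lead cluster 13, so some were also summed without clustering, and these were higher on day 1 too. Over all cells of a library, Thbs1 stood at 1299 CPM on day 1 against 15.6, Arg1 at 278 against 18.9, Cxcl3 at 457 against 3.08, Spp1 at 736 against 43.4 and Fabp5 at 937 against 27.6. These sums include neutrophil-like and other cells, whose shares differed between the libraries. They do not show which cells carried the genes. Arg1 UMIs were found in 40.0% (36.2 to 43.8) of the day 1 pool at a median of 14272 UMIs per cell, against 11.7% (6.39 to 19.2) of lymphocyte-like cells, which should lack it, at 6215. Thinned to 5000 UMIs per cell, which left out 35 pool cells and 20 lymphocyte-like cells, the shares were 33.4% and 12.1%. Of the 270 neutrophil-like cells, 7.04% (4.29 to 10.8) had an Arg1 UMI, and 31.9% (19.1 to 47.1) of the 47 deepest, since thinning left out 223. With no injury named the pool's share was 0.549%, below the lymphocyte-like 2.56%. On days 4 and 7 it was 1.42% and 0.782%, again below the lymphocyte-like 5.71% and 3.07%, so the pool's share stood above that of lymphocyte-like cells on day 1 alone. Within the day 1 pool, Arg1 was at 815 CPM in monocyte-like cells and at 52.9 in macrophage-like cells, below the 112 of lymphocyte-like cells. In GRCm38, Arg1 (ENSMUSG00000019987) lies on chromosome 10 from 24915221 to 24927484, Thbs1 (ENSMUSG00000040152) on chromosome 2 from 118111876 to 118127133 and Cxcl3 (ENSMUSG00000029379) on chromosome 5 from 90786103 to 90789600.

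Inflammatory and tissue-remodelling lists were higher in the day 1 pool, and macrophage lists lower. The inflammatory cytokine and chemokine list had a median of 1.94 (1.83 to 2.05), with 8 of 14 members at least 2-fold higher. Its neutrophil chemokine gene Cxcl2 stood at 8672 against 2312 CPM and Il1b, the pyrogenic cytokine interleukin 1 beta, at 3436 against 284. The lipid-associated and matrix list had a median of 1.65 (1.499 to 1.89) with 9 of 14 members higher. Among them were the galectin gene Lgals3 at 6.21-fold (5.87 to 6.58) and the lysosomal protease gene Ctsd at 2.32-fold (2.20 to 2.45). Spp1, the secreted matrix protein osteopontin, stood at 1303 against 54.1 CPM, but 98.0% of its UMIs with no injury named were in 1 cell, so no ratio is given. Of the glycolysis and hypoxia list, median 1.00 (0.89 to 1.16), 6 of 13 members were higher, including Gapdh at 2.60-fold (2.44 to 2.76) and Pkm at 2.99-fold (2.74 to 3.27). The interleukin 6 family gene Osm was 9.45-fold (7.87 to 11.4) higher in a growth factor list with a median of 0.29 (0.19 to 0.67). The chemokine genes Ccl6 and Ccl9 were 2.995-fold (2.88 to 3.12) and 2.31-fold (2.21 to 2.42) higher. Medians were -1.22 (-1.46 to -1.12) for the Lyve1-type macrophage list (10 of 15 members at least 2-fold lower) and -1.15 (-1.29 to -0.99) for the MHC class II list (5 of 8). They were -0.92 (-1.04 to -0.72) for the list for uptake of dead cells (5 of 12) and -0.89 (-0.93 to -0.84) for tissue macrophage identity (7 of 14). Of their members, the lipid carrier gene Apoe was 2.98 times (2.95 to 3.02) lower, the complement genes C1qa and C1qb 2.33 times (2.29 to 2.38) and 2.08 times (2.03 to 2.12), and the selenium carrier gene Selenop 2.88 times (2.80 to 2.95). Cd74 and H2-Eb1 of MHC class II were 2.501 times (2.46 to 2.54) and 3.16 times (3.08 to 3.24) lower, and the scavenger receptor gene Cd163 2.02 times (1.90 to 2.14). In macrophage-like cells alone Cd163 was not lower, at 0.10 on the log2 scale, and C1qa, C1qb and Selenop were less than 2-fold lower. The platelet factor gene Pf4 stood at 4158 against 4412 CPM. The alternative activation, interferon response and cholesterol lists had medians of -0.013, 0.0078 and 0.23. Those of immediate early genes and of chemokines for lymphocytes and eosinophils were -0.57 and -0.45, and the proliferation list 0.46.

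MHC class II genes were also lower on day 1 within cluster 0. The Lyve1-type list had a median of 0.0017 (-0.15 to 0.19) in cluster 0 alone. Its median of 0.072 (-0.14 to 0.11) in cluster 5 follows from the clustering, since Lyve1, Fcna, Folr2, Vsig4, Gas6 and Cd163 lead that cluster. Cells with a Lyve1, Folr2 or Cd163 UMI made up 85.7% of the pool with no injury named and 42.5% on day 1, against 15.4% and 11.7% of lymphocyte-like cells. Median depths were 14414 and 14272 UMIs in the pool and 9287 and 6215 in lymphocyte-like cells. Among macrophage-like cells alone, cells with such a UMI made up 88.1% and 83.6%. Thinned, the pool's shares were 83.1% and 37.5% against 16.2% and 5.50%. In cluster 0 (89 cells on day 1, 56 with no injury named), the MHC class II list had a median of -1.39 (-1.5 to -1.32) with 6 of 8 members at least 2-fold lower. H2-Aa, an antigen-presenting chain, stood at 2779 (2693 to 2868) against 10032 (9809 to 10259) CPM, and Cd74, its chaperone, was 2.84 times (2.77 to 2.91) lower. Retnla, a product of alternatively activated macrophages, was 8.21 times (6.77 to 10.0) lower in cluster 0 and 2.39 times (2.10 to 2.71) in cluster 5. The lectin gene Mgl2 was 3.43 times (3.01 to 3.90) and 2.66 times (2.33 to 3.03) lower. Cluster 5 (121 and 83 cells) had Il4ra, the interleukin 4 receptor, 4.46-fold (3.72 to 5.37) higher, Osm 2.88-fold (2.12 to 3.97) and the lysosomal protease gene Ctsl 2.62-fold (2.34 to 2.96) higher. Apoe was 2.86 times (2.80 to 2.93) and the eosinophil-attracting chemokine gene Ccl24 4.18 times (3.62 to 4.84) lower there. Lgals3 was higher in both clusters, 2.12-fold (1.92 to 2.35) in cluster 0 and 2.43-fold (2.16 to 2.75) in cluster 5, in lipid-associated and matrix lists with medians of 0.94 (0.82 to 1.12) and 1.32 (1.17 to 1.44). The classical monocyte list was nearer to 0 within clusters 0 and 5, with medians of 0.70 (0.51 to 1.53) and 0.47 (0.0011 to 0.80). In macrophage-like cells alone, which include further clusters, it was 4.83 (3.08 to 5.09), above that of the pool, with 4 of 11 members at 0 UMIs on a side. The inflammatory list did not keep its direction in cluster 0, where its median was -0.28 (-0.37 to -0.14). MHC class II transcripts of cluster 5 did not exceed those in lymphocyte-like cells with no injury named or on days 1 and 4, and are not compared there.

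**Figure D2:**
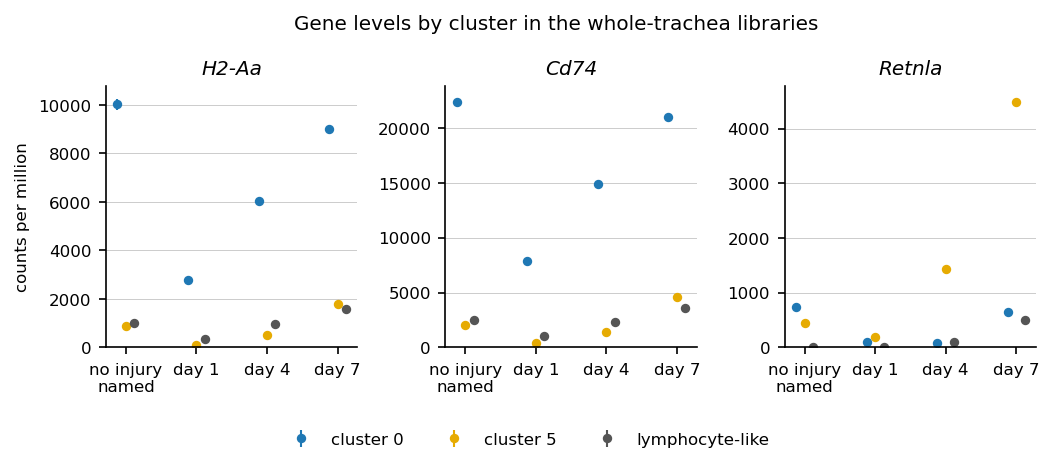
CPM (y axes) of H2-Aa, Cd74 and Retnla in cluster 0, cluster 5 and lymphocyte-like cells of the 4 whole-trachea libraries (x axes); points are levels and bars, mostly shorter than the points, exact Poisson 95% intervals. H2-Aa in cluster 0 stood at 10032 with no injury named, 2779 on day 1, 6023 on day 4 and 9005 on day 7, and Retnla in cluster 5 at 447, 187, 1434 and 4476.

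Of the 8 genes that the rule named as lower on day 1, 7 had over 50% of their UMIs with no injury named in 1 cell: the bone-resorbing protease gene Ctsk, Acp5, Mt3, Igfbp7, Mmp9 and the secretory cell genes Scgb1a1 and Bpifa1. Without the highest cell of each library the log2 ratio of Acp5 turned from -3.48 to 2.64 and that of Ctsk from -7.15 to 1.15. The others stayed lower but nearer to 0, Igfbp7 from -5.42 to -2.51, Scgb1a1 from -4.78 to -1.92 and Mmp9 from -3.92 to -2.29, with Bpifa1 likewise at least 2-fold lower, and Mt3 had no value left. With most of their UMIs in 1 cell, the 7 are not read as differences of the pool. The other gene, Serpinf1, was 13.3 times (9.34 to 19.3) lower, but its levels did not exceed those in lymphocyte-like cells. With genes carried by few cells left out, the rule also gave Siglech, Fxyd2, Bmp2, Mgl2 and Bank1, which were 10.3 times, 7.42 times, 7.26 times, 5.39 times and 5.43 times lower, and Pla2g2d and St3gal6, which lay at the lymphocyte-like level. Among lists for RNA of other cells, the neutrophil list had a median of 3.81 (2.38 to 4.85) over 5 members whose day 1 levels lay near or below those in lymphocyte-like cells, and -0.54 with classes given per cell. The epithelial list had a median of -4.03, the fibroblast list -2.21, the erythroid list -5.66 and the lymphocyte list -1.18, each over 5 or fewer members.

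By day 4 the pool lay close to the library with no injury named. The monocyte genes of day 1 were no longer higher as a group. The classical monocyte list had a median of -0.12 (-0.32 to -0.0053) with 1 of 8 members at least 2-fold higher and 2 lower. It was 0.43 in cluster 0, -0.48 in cluster 5 and 0.38 in macrophage-like cells alone. Thbs1 stood at 19.6 against 21.9 CPM, and the alternative activation list was at -0.0067 (-0.085 to 0.069). The rule named 3 genes as higher. Ccl8, a chemokine gene, stood at 595 (577 to 614) against 239 (221 to 259) CPM, 2.49-fold (2.29 to 2.71) higher. Cxcl1, a neutrophil chemokine gene, stood at 182 against 76.0, 2.40-fold (2.07 to 2.79) higher. Hspa1a, a heat shock gene, stood at 914 against 447, 2.04-fold (1.92 to 2.18) higher. Ccl8 with no injury named lay near the 207 CPM of lymphocyte-like cells, with an interval not wholly above theirs. Hspa1a was also higher in those cells, 359 against 196. In cluster 5, Retnla was 3.21-fold (2.93 to 3.51) higher and Ccl8 6.35-fold (5.38 to 7.54) higher. Cluster 0 (243 cells against 56) had lower antigen presentation and chemokine genes. H2-Aa was 1.67 times (1.62 to 1.71) and H2-Eb1 1.68 times (1.64 to 1.73) lower. The monocyte chemokine genes Ccl7 and Ccl2 were 2.48 times (2.22 to 2.78) and 1.78 times (1.63 to 1.95) lower, Ccl3 2.17 times (2.00 to 2.35) and the interferon-induced chemokine gene Cxcl10 3.19 times (2.72 to 3.75). The cluster's MHC class II list had a median of -0.62 (-0.64 to -0.47) and its inflammatory list -0.64 (-0.85 to -0.52), with 4 of 12 members at least 2-fold lower.

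The other lists of the day 4 pool had medians between -0.26 for chemokines for lymphocytes and eosinophils and 0.25 for lipid-associated and matrix genes. Their most abundant members stood within 2-fold of the library with no injury named. These were Pf4 and Selenop of the Lyve1-type list, Cd74 and H2-Eb1 of MHC class II, and Mrc1 and Cd163 of alternative activation. Others were Cxcl2 and Ccl4 of the inflammatory list, Grn and Igf1 of growth factors, Timp2 and Ctsd of the lipid and matrix list, Bst2 and Cxcl10 of the interferon response, and Gapdh and Aldoa of glycolysis. Also within that range were Apoe and Npc2 of cholesterol handling, C1qa and C1qb of uptake, Ccl6 and Ccl9 of the chemokines, Tubb5 and Pcna of proliferation, Junb and Fos of the immediate early list, and F13a1 and S100a4 of the monocyte list. All 8 genes that the rule named as lower, Ctsk, Mt3, Fabp4, Acp5, Igfbp7, Ccl22, Ccl17 and Atp6v0d2, had over 50% of their UMIs with no injury named in 1 cell and are not read as differences. With genes carried by few cells left out, 2 genes passed as lower, which are not named here. For Acp5, Ccl22, Ccl17 and Atp6v0d2 the direction also depended on which cells were used. Ccl17 went from -3.20 to -0.38 without the highest cell of each library and to 3.71 without cells rich in epithelial RNA. Lists for RNA of other cells had medians of -1.11 for neutrophil, 0.37 for epithelial, -0.89 for fibroblast, -6.70 for erythroid and 0.24 for lymphocyte genes, each over 5 or fewer members.

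On day 7 Retnla and some interferon-induced genes stood higher. Retnla was at 2423 (2390 to 2456) against 425 (400.5 to 450.1) CPM, 5.70-fold (5.37 to 6.06) higher, and in cluster 5 (274 cells against 83) 10.0-fold (9.19 to 10.9) higher. The interferon response list had a median of 0.49 (0.20 to 0.56), with 4 of 15 members at least 2-fold higher and 1 lower. Its median was 1.37 (0.74 to 1.85) in cluster 0 and 0.76 (0.28 to 0.91) in cluster 5, with Irf7, Ifi47 and Zbp1 of cluster 0 at the level of lymphocyte-like cells. Cluster 6, led by the interferon-induced genes Rsad2, Ifit3 and Ifit1, held 3.85% (1.56 to 7.76) of the pool with no injury named and 7.98% (6 to 10.4) on day 7, intervals that overlap. Iigp1, an interferon-induced GTPase gene, was 9.66-fold (6.76 to 14.3) higher in the pool and 5.13-fold (3.10 to 9.12) in cluster 5, and Gbp2, another such GTPase gene, 4.16-fold (2.94 to 6.04) higher in the pool. Both exceeded the lymphocyte-like level on day 7 but not with no injury named. Ccl8 was 3.97-fold (3.67 to 4.31) higher in the pool and 4.01-fold (3.39 to 4.76) in cluster 5. The interferon-induced chemokine gene Cxcl10 went the other way, 2.11 times (1.91 to 2.34) lower, and the zinc transporter gene Slc39a1 was 2.01 times (1.70 to 2.37) lower. Hspa1a was 3.05-fold (2.88 to 3.24) and the lysozyme gene Lyz1 2.30-fold (1.96 to 2.71) higher. Hspa1a was also higher in lymphocyte-like cells, 509 against 196 CPM. In GRCm38, Retnla (ENSMUSG00000061100) lies on chromosome 16 from 48842551 to 48844461, Iigp1 (ENSMUSG00000054072) on chromosome 18 from 60376027 to 60392634 and Ccl8 (ENSMUSG00000009185) on chromosome 11 from 82115185 to 82116799.

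The MHC class II list had a day 7 median of 0.45 (0.44 to 0.50) with 0 of 8 members at least 2-fold higher, Cd74 at 12146 against 8875 CPM and H2-Eb1 at 5637 against 4112. In cluster 0, the main carrier of these genes, the median was -0.072 (-0.092 to 0.0044), and in lymphocyte-like cells H2-Aa stood at 1570 CPM against 1023. The classical monocyte list was at -0.17 (-0.24 to -0.12), but at 0.86 in macrophage-like cells alone, -0.88 in thinned cells and -1.19 with the mean of cells. The alternative activation list was at -0.11 (-0.15 to -0.034), with 1 of 9 members higher, Retnla. The other lists lay between -0.30 for inflammatory genes and 0.21 for proliferation genes. Of their most abundant members, Pf4, Selenop, Mrc1, Cxcl2, Ccl2, Grn, Igf1, Timp2, Ctsd, Bst2, Gapdh, Aldoa, Apoe, Npc2, C1qa, C1qb, Ccl6, Ccl9, Tubb5, Pcna, Junb, Fos, F13a1 and S100a4 stood within 2-fold of the library with no injury named. Of the 12 genes that the rule named as higher, 11 had over 50% of their day 7 UMIs in 1 cell and are not read as differences of the pool. They were Ccl21a, Igfbp5 and the secretory cell genes Scgb1a1, Cyp2a5, Scgb3a2, Cyp2f2, Bpifa1, Wfdc2, Lypd2, Scgb3a1 and Reg3g. Leaving out the highest cell of each library took Scgb1a1 from 39.8-fold to 5.23-fold higher and turned Wfdc2 and Lypd2 to -0.0054 and -0.073 on the log2 scale. The stricter cell filter turned Scgb1a1 to -1.44, and Cyp2a5, Scgb3a2, Cyp2f2, Bpifa1, Scgb3a1 and Reg3g with it. All 8 named as lower, Ctsk, Mt3, Acp5, Ccl17, Ccl22, Atp6v0d2, Mmp9 and Spp1, likewise rested on 1 cell with no injury named and are not read. Here too the direction depended on which cells were used, for Acp5, Ccl17, Ccl22, Atp6v0d2 and Spp1. Ccl22 went from -4.94 to -0.85 without the highest cell of each library and to 0.16 without cells rich in epithelial RNA. Medians of the lists for RNA of other cells were 3.30 for epithelial, -0.63 for neutrophil, -0.32 for fibroblast, -5.98 for erythroid and 1.30 for lymphocyte genes, each over 7 or fewer members.

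**Figure D3:**
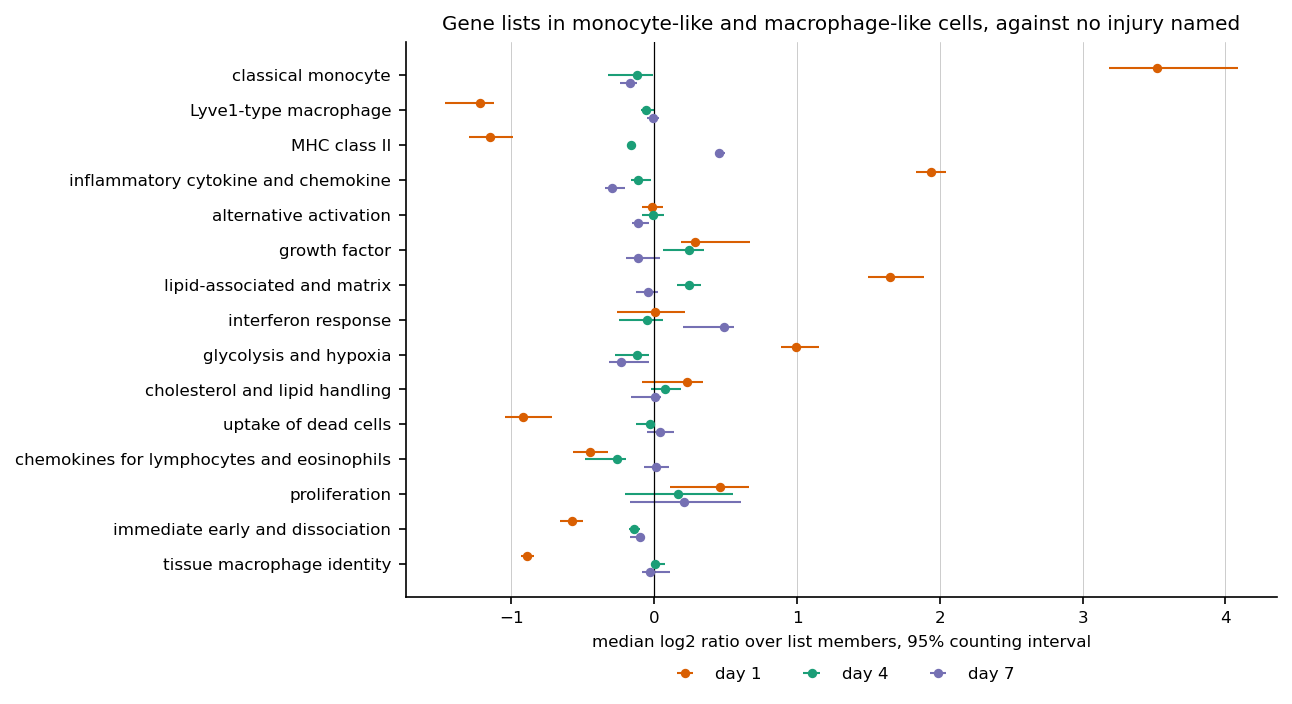
Median log2 ratio over the members of 15 gene lists (x axis) in monocyte-like and macrophage-like cells on days 1, 4 and 7 against the library with no injury named; bars are 95% counting intervals. Day 1 medians ran from -1.22 for the Lyve1-type macrophage list to 3.52 for the classical monocyte list, and those of days 4 and 7 from -0.30 to 0.49.

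The comparison of tracheal epithelium with tracheal mesenchyme asks whether macrophages differ between the layers of the airway wall. Macrophage-like cells of the epithelium carried fewer Lyve1-type transcripts and more MHC class II transcripts than those of the mesenchyme. The size of the MHC class II difference depended on the mesenchymal cluster compared. No background for these genes was available in the epithelium, where lymphocyte-like cells include B cell-like cells. Because markers of another class led the mesenchymal cluster 11 more than its own did, clusters were compared by number. Cluster 0, led by Scgb1a1, held 56 of the 62 macrophage-like cells of the epithelium. It was set against the mesenchymal clusters 11 (255 cells, led by Folr2) and 15 (133 cells, led by Lyz1). Scgb1a1 UMIs were also found in 96.1% of lymphocyte-like cells of the epithelium library. Cluster 0 may therefore rest in part on background RNA of that library, which was not tested. The class of cluster 0 rests on a score of 1.03, just above the minimum of 1 set after the data were seen. At resolution 1.5 the macrophage-like cells of the epithelium number 5, and with no cell filter 8. Against cluster 15 the MHC class II list had a median of 0.75 (0.66 to 0.79), with 2 of 8 members at least 2-fold higher. Cd74 was 1.63-fold (1.58 to 1.68) and H2-Aa, at 10420 (9952 to 10903) CPM in cluster 0, 1.57-fold (1.49 to 1.66) higher. Against cluster 11 the list's median was 3.04 (2.82 to 3.21), but Cd74 and H2-Aa of that cluster did not exceed RNA found in other cells, so this value is not read as a size of difference. Itgax, the CD11c integrin chain of dendritic cells and of macrophages at mucosal surfaces, was 46.6-fold (18.3 to 152) higher than in cluster 11 and 24.6-fold (10.3 to 71.5) than in cluster 15, and Il1b 22.6-fold (11.7 to 47.0) and 7.16-fold (4.25 to 12.3) higher. Against cluster 11, Fn1 was also 15.96-fold (8.57 to 31.2) and the monocyte chemokine receptor gene Ccr2 4.55-fold (2.93 to 7.00) higher.

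Some chemokine genes and the mannose receptor gene stood lower in epithelial cluster 0. The monocyte-attracting chemokine gene Ccl7 was 94.3 times (32.2 to 458) lower in epithelial cluster 0 than in cluster 11; its level in cluster 15 lay within background. Ccl2 was 22.2 times (11.6 to 48.6) and 12.7 times (6.65 to 28.0) lower. Mrc1, that receptor, was 29.1 times (13.3 to 79.3) and 12.7 times (5.78 to 34.9) lower, and Ccl6 7.18 times (5.56 to 9.43) and 3.39 times (2.61 to 4.48) lower. Sepp1, the selenium carrier gene named Selenop in the other libraries, was 5.67 times (4.79 to 6.78) and 2.53 times (2.12 to 3.04) lower. Gas6, which bridges dead cells to phagocytes, was 68.3 times (18.8 to 565) lower than in cluster 11, and Pf4 30.7 times (19.6 to 51.1) lower than in cluster 15. Ccl8 and the complement receptor gene Vsig4 had 0 UMIs in epithelial cluster 0 and were at least 16.4 times lower and at least 11.8 times lower than in cluster 11. The Lyve1-type list had medians of -4.36 (-5.06 to -3.84) against cluster 11, which 5 of its members lead (Lyve1, Folr2, Fcna, Cd163 and Pf4), and -2.63 (-3.11 to -1.79) against cluster 15. The inflammatory list had -1.20 (-1.64 to -0.72) and -2.02 (-2.16 to -0.85). In GRCm38, Itgax (ENSMUSG00000030789) lies on chromosome 7 from 128129547 to 128150657, Ccl7 (ENSMUSG00000035373) on chromosome 11 from 82045712 to 82047525 and H2-Ab1 (ENSMUSG00000073421) on chromosome 17 from 34257689 to 34269419.

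Over all macrophage-like cells, as planned, the medians were 1.58 (1.44 to 1.63) for MHC class II (8 of 8 members at least 2-fold higher, percentile 99.99) and -2.98 (-3.19 to -2.61) for the Lyve1-type list (14 of 15 lower, percentile 0). Without cluster 11 the MHC class II median was 0.65. Other lists had medians of -1.32 for inflammatory, -1.17 for alternative activation, -0.97 for uptake, -0.71 for growth factor, -0.66 for glycolysis and hypoxia, and 0.59 for classical monocyte genes. The lymphocyte and eosinophil chemokine list had -1.25 (-1.64 to 0.61), an interval that spans 0, and turned to 0.53 without the highest cell of each gene. The lipid and matrix, interferon, cholesterol, proliferation, immediate early and identity lists lay between -0.33 and 0.15. Among abundant members, Cxcl2 was 3.60 times (3.07 to 4.24) and Ccl9 3.15 times (2.59 to 3.88) lower, and Apoe stood at 6056 against 8636, C1qb at 4413 against 4916, Lgals3 at 998 against 623 and Retnla at 1351 against 1030 CPM. The rule also named Itgax, Ccl7, Ccl2, Ccl8, Pf4, Vsig4 and Lyve1, given or listed above. The direction of Vsig4 rests on cluster 11: without it the ratio was 1.29 on the log2 scale, a value set by the floor for 0 UMIs. The rule further named Csrnp1, at 0 UMIs in the epithelium and at least 9.23 times lower, Ltf, with 96% of its mesenchymal UMIs in 1 cell, and the natural killer cell adaptor gene Sh2d1b1, 27.7-fold (11.97 to 71.7) higher. The rest of its higher genes were markers of other cells: the alveolar surfactant genes Sftpc and Sftpa1, the secretory and basal cell genes Scgb1a1, Scgb3a2, Bpifa1, Wfdc2 and Krt15, and Inmt, Epas1 and Ccl5. Krt15, Bpifa1 and Wfdc2 had over 50% of their epithelial UMIs in 1 cell. Of the markers, Sftpc, Scgb1a1, Sftpa1 and Inmt did not exceed lymphocyte-like cells of the same library. There Scgb1a1 stood at 1406 CPM against 1387 in macrophage-like cells. The epithelial list had a median of 4.99, the lymphocyte list 3.27, the fibroblast list 0.36 and the neutrophil list -0.90; no erythroid gene was measured.

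Tissue, digestion and sort cannot be told apart here, since the epithelium alone was released with trypsin and sorted without F4/80. The median log2 ratio over 2036 genes was -0.17, so scaling by the median of ratios makes each log2 ratio higher by that size. The mesenchyme library held no lymphocyte-like cells, and its 34 type 2 innate lymphoid-like cells carried H2-Aa at 5644, Cd74 at 14662, Lyve1 at 266 and Ccl7 at 693 CPM. H2-Aa (1248) and Cd74 (2859) in cluster 11 and Ccl7 in cluster 15 (613) therefore did not exceed RNA found in other cells, while H2-Aa in cluster 15 (6642) and Ccl7 in cluster 11 (1579) did. H2-Aa in cluster 15 did so by little. For H2-Aa and Cd74, cluster 11 lay below the innate lymphoid-like cells, so the level of those cells is not a background shared by all cells. Cluster 0 also held 4 of the 7 macrophage-like cells of the lung and 8 of the 396 of the mesenchyme. The epithelium library held cells of lung type, so lung macrophages in cluster 0 are not excluded. The comparison may therefore not be one between layers of the airway wall alone.

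**Figure D4:**
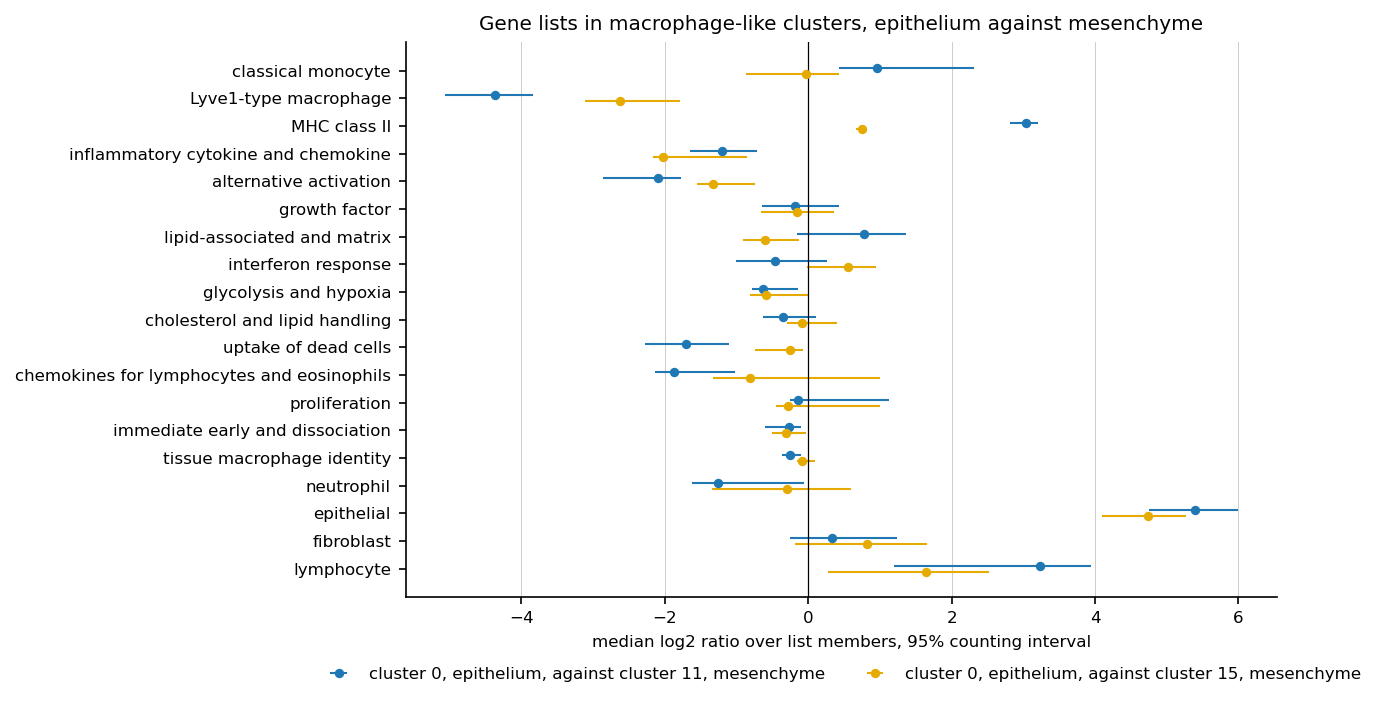
Median log2 ratio over the members of 19 gene lists (x axis) in cluster 0 of the epithelium against clusters 11 and 15 of the mesenchyme; bars are 95% counting intervals. The MHC class II list stood at 3.04 and 0.75, and the Lyve1-type macrophage list at -4.36 and -2.63. The value of 3.04 is not read as a size of difference. Cd74 and H2-Aa in cluster 11 did not exceed their levels in other cells of the mesenchyme, and whether they were background was not settled.

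The comparison of tracheal mesenchyme with lung asks how airway macrophages differ from those of the lung, both sorted on CD45 and F4/80. The lung library held 210 alveolar macrophage-like cells and 7 other macrophage-like cells. Of the 210, 28 lay in cluster 17, which Cd8b1 and Bcl11b led beside Fabp1 and Chil3. Its second class was T cell (score 0.976), so mixed cells among the 210 are not excluded. In those 7 cells Pf4 was 1163 CPM against 5352 in 396 cells of the mesenchyme, 4.60-fold (3.32 to 6.57) higher there. Sepp1 was 3.55-fold (2.47 to 5.31) higher in the mesenchyme, and Cd74 and H2-Aa were 2.65 times (2.47 to 2.85) and 2.65 times (2.34 to 2.98) lower. The Lyve1-type list had a median of 2.03 (1.54 to 2.505), with 12 of 15 members at least 2-fold higher, and the MHC class II list -1.49 (-1.72 to -1.35), with 8 of 8 lower. Of the Lyve1-type members, 7 had 0 UMIs on a side. With 3 lung cells at Leiden resolution 1.5 the Lyve1-type median was 0.67, and with 6 when classes were given per cell that of MHC class II was -0.18. No other genes are named from 7 cells: at that number the rule also picked 1133 of 2387 genes that were simulated without a difference.

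Against alveolar macrophage-like cells, a choice made after the data were seen, mesenchymal macrophages carried more monocyte chemokine transcripts and fewer transcripts of Lpl and Fabp5. Cluster 11 (255 cells) had Ccl2 19.9-fold (14.4 to 28.3) and Ccl7 82.7-fold (48.2 to 156) higher than the lung's cluster 12 (169 cells), and cluster 15 (133 cells) had Ccl2 11.5-fold (8.22 to 16.4) higher. Gas6 was 173-fold (59.0 to 840.2) and the scavenger receptor gene Stab1 154-fold (42.4 to 1274) higher in cluster 11, and Pf4 246-fold (129.7 to 539.8) in cluster 15. Lpl, the lipoprotein lipase, was 59.9 times (43.9 to 83.8) lower in cluster 11 and 11.6 times (9.74 to 14.0) in cluster 15, and Fabp5 78.4 times (43.4 to 158) and 36.5 times (21.9 to 65.6). The tetraspanin gene Cd9 was 31.4 times (26.5 to 37.5) and 17.5 times (14.9 to 20.7), and Gpnmb, a lysosomal glycoprotein gene, 61.0 times (25.7 to 190.1) and 96.8 times (26.4 to 805) lower. Lipid-associated and matrix lists had medians of -3.54 (-4.05 to -2.51) and -1.12 (-1.39 to -0.86) in cluster 11 and cluster 15. The Lyve1-type list had a median of 2.80 (2.57 to 3.90) in cluster 15, with 4 members at 0 UMIs on a side, and its value in cluster 11, which 5 of its members lead, is not read. The MHC class II list turned direction, with medians of 2.92 (1.82 to 3.18) and 4.59 (3.97 to 4.82). Cd74 was 11.2-fold (9.60 to 13.1) and 73.5-fold (63.3 to 85.9) higher. The cholesterol and lipid handling list had medians of -0.89 (-1.39 to -0.54) and -1.35 (-1.91 to -0.76), but not all lipid genes were lower. Cd36, a fatty acid transporter gene, was 2.07-fold (1.80 to 2.38) higher in cluster 11, and Apoe was 31.5-fold (27.8 to 35.8) higher in the mesenchyme than in all 210 alveolar macrophage-like cells. Against those 210 cells, the Lyve1-type median was 5.93 (5.18 to 6.07) and that of MHC class II 3.49 (3.06 to 4.17). Of the 396 mesenchymal cells in that comparison, 255 were of cluster 11. Both medians therefore carry the limits of cluster 11 and are not read as sizes of difference. Ccl2, Ccl7, Pf4, Gas6 and Stab1 in cluster 12 did not exceed lymphocyte-like cells of the lung and are not read as expressed there. The level of H2-Aa in cluster 11 lay below that of the mesenchyme's own innate lymphoid-like cells, so the cluster 11 values of MHC class II are not read as a difference in expression. H2-Aa in cluster 15 lay above those cells by little, so the size of its MHC class II values is uncertain. In the 7-cell comparison the remaining lists had medians from -3.60 for fibroblast to 0.85 for alternative activation genes, each but tissue macrophage identity with at least 1 member at 0 UMIs on a side.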

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

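The tests in this part were chosen only after the result was seen, except those of free RNA and of uptake for Scgb1a1, the stricter cell filter and classes given per cell, which were set before. Some lists stood on opposite sides of the library with no injury named on different days by at least 1 on the log2 scale on both, and the difference was not tested in any case. All that did so were lists for RNA of other cells. The neutrophil list had a median log2 ratio of 3.81 on day 1 and -1.11 on day 4, the epithelial list -4.03 on day 1 and 3.30 on day 7, and the lymphocyte list, over 1 and 2 members, -1.18 on day 1 and 1.30 on day 7. None of the 3 held under every alternative. The epithelial list turned to -1.77 on day 7 with the stricter cell filter, the lymphocyte list to -1.49 on day 7 in cluster 5, and the neutrophil list to -0.54 on day 1 with classes given per cell, to -1.31 on day 1 in cluster 0 and to 0.52 on day 4 in cluster 5. Other lists changed sides with a smaller value on 1 of the days. Medians of the classical monocyte list were 3.52 on day 1 and -0.17 on day 7, the inflammatory list 1.94 and -0.30, and the MHC class II list -1.15 and 0.45. The days share the library with no injury named, so they are not independent.

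Secretory cell transcripts of the day 7 pool rested largely on 1 cell: Scgb1a1, a club cell product, was 39.8-fold (34.5 to 46.2) higher with all cells and 5.23-fold higher without the highest cell of each library, which argues for 1 secretory cell or doublet in the pool as the main source, although the CD45 enrichment should remove a secretory cell. With the stricter cell filter its log2 ratio turned from 5.31 to -1.44, so what is left has no settled direction in summed UMIs. With the cell filter first used, 2.91% (0.951 to 6.65) of thinned pool cells had a Scgb1a1 UMI with no injury named. On day 7 that share was 10.6% (8.23 to 13.3), so by cells with a UMI it was higher. For what is left, free RNA remains a candidate explanation, since 6.34% (2.94 to 11.7) of thinned lymphocyte-like cells had a Scgb1a1 UMI against 10.6% (8.23 to 13.3) of thinned pool cells, intervals that overlap. Uptake of secretory cell material by macrophages would need the share to be higher in the pool, 10.6%, beyond these intervals, so it is neither shown nor excluded. No biological explanation other than uptake was tested.

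The epithelium library held cells of lung type. The 16 cells of a cluster led by the surfactant gene Sftpc carried 91.7% (91.2 to 92.1) of that library's 18374 Sftpc UMIs, which argues against free RNA as the main source. An exchange of labels between epithelium and lung is argued against by the alveolar macrophage-like cells, 46.8% (42.1 to 51.5) of lung cells and 2.15% (0.870 to 4.39) of the epithelium library. Cells of lung tissue in the suspension may be the source, since 7 alveolar macrophage-like cells were found in the epithelium library and 0 in the mesenchyme library. The only 3 epithelial-like cells of the epithelium library also shared a cluster with 5 cells of the lung and 0 of the mesenchyme. That cluster was led by Ager, and the airway genes Scgb1a1 and Krt5 were not among its leading genes. The CD45 sort of the epithelium library should remove surfactant-expressing cells of any origin, and why it did not was not tested. A presence of such cells in the trachea itself was not tested.

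Arg1 stood at 490.5 CPM (477 to 504) in the day 1 pool. Free RNA as the whole source is argued against by the 112 (92.0 to 134) CPM in lymphocyte-like cells of that library. A larger share of monocyte-like cells alone cannot be told apart from a difference in those cells and stays open. It needs such cells to carry Arg1 alike in every library. Thinned, 4.17% (0.105 to 21.1) of the 24 monocyte-like cells of the other 3 whole-trachea libraries had an Arg1 UMI, against 48.0% (43.0 to 53.0) on day 1. This decides nothing, since Arg1 is among the genes that lead this cluster, those 24 cells are few and each day was 1 library. Earlier forms of this test used macrophage-like cells, with a ratio of 7.08 on the log2 scale for Arg1, day 1 against no injury named, and a level of 52.9 CPM (46.3 to 60.2). They were replaced after their results were seen, because that level is within background and says nothing about monocyte-like cells. Whether monocytes brought Arg1 with them or made it in the trachea was not tested.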

How the results depend on the processing

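The tests in this part that were chosen only after the result was seen are those without cells rich in epithelial RNA, the highest doublet scores, the highest cell of each gene or the Lyve1 cluster. Those with the cluster led by Retnla and Mmp12, against lung alveolar macrophage-like cells and of clusters by number were also chosen then. No paired analysis was possible because each group held 1 library, and no difference was tested. A value counts as unmoved when it lies within the counting interval first found. Over all alternatives run, 31 of 36 pool shares, 93 of 162 medians of the lists that the comparisons were set up for, 983 of 1408 medians of the other lists and 2404 of 3338 gene ratios stayed within it. Of the values at least 2-fold from 1 at first, 74 of 77, 413 of 433 and 1972 of 2054 kept their direction, and 3, 20 and 82 turned. Monocyte-like cells alone were not compared, with 6 cells in the library with no injury named. Epithelium against mesenchyme had no value at resolution 1.5 (5 cells) or without a filter (8 cells), and mesenchyme against lung none with the stricter filter (0 lung cells). Depth limits the epithelium most, at a median of 2133 UMIs per barcode, and 7 lung cells limit the values between mesenchyme and lung other than those against alveolar macrophage-like cells or cluster 12. Lyve1-type medians of whole-trachea cluster 5 and tissue cluster 11 follow in part from the clustering, since members of the list lead both.

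Values of genes and lists are log2 ratios, and except where a single cell is named as left out the cause was not tested. With no cell filter, Sparc went from -2.46 to 0.088 on day 4, Sparc from -1.13 to 0.42 on day 7, and the Lyve1-type list from 2.03 to 0.71 and the MHC class II list from -1.49 to -0.87 between mesenchyme and lung. With the stricter cell filter, Ctsk went from -7.15 to 1.52 and Acp5 from -3.48 to 2.74 on day 1, and Acp5 from -4.82 to 1.03 and Atp6v0d2 from -2.91 to 0.29 on day 4. The classical monocyte list went from -0.17 to -0.45, the epithelial list from 3.30 to -1.77, Scgb1a1 from 5.31 to -1.44 and Cyp2a5 from 6.82 to -0.42 on day 7. Scgb3a2 went from 4.77 to -1.62, Cyp2f2 from 5.09 to -1.56, Bpifa1 from 4.35 to -1.77 and Wfdc2 from 4.50 to -1.95 on day 7. Lypd2 went from 5.17 to -0.74, Scgb3a1 from 3.30 to -3.06, Reg3g from 3.42 to -2.25 and Atp6v0d2 from -3.69 to 0.19 on day 7. Spp1 went from -2.26 to 1.77 on day 7, and the Lyve1-type list from -2.98 to -3.21 and the MHC class II list from 1.58 to 2.33 between epithelium and mesenchyme. With called doublets removed, the classical monocyte list went from -0.17 to -0.11 on day 7, the MHC class II list from -1.49 to -0.90 between mesenchyme and lung, and the MHC class II list from 1.58 to 1.06 between epithelium and mesenchyme. At resolution 0.4, the MHC class II list went from -1.49 to -0.93 between mesenchyme and lung, and the MHC class II list from 1.58 to 0.80 between epithelium and mesenchyme. At resolution 1.5, Acp5 went from -3.48 to 2.34 on day 1, Acp5 from -4.82 to 1.33 and Atp6v0d2 from -2.91 to 0.82 on day 4, and the alternative activation list from -0.11 to -0.16 on day 7. Acp5 went from -5.98 to 0.16, Atp6v0d2 from -3.69 to 0.052 and Spp1 from -2.26 to 3.18 on day 7, and the Lyve1-type list from 2.03 to 0.67 between mesenchyme and lung. Mertk went from 1.32 to -0.055 between mesenchyme and lung, and the pool share from 43.3% to 35.2% on day 1. With classes given per cell, the classical monocyte list went from 3.52 to 3.02, the neutrophil list from 3.81 to -0.54, Ctsk from -7.15 to 0.19 and Mt3 from -7.48 to 0.58 on day 1. Acp5 went from -3.48 to 2.22 on day 1, and the classical monocyte list from -0.12 to -0.46, the alternative activation list from -0.0067 to -0.11 and Acp5 from -4.82 to 0.39 on day 4. Ccl17 went from -3.20 to 2.99, Atp6v0d2 from -2.91 to 0.31 and Sparc from -2.46 to 0.048 on day 4, and the classical monocyte list from -0.17 to -0.49 on day 7. The alternative activation list went from -0.11 to -0.18, Igfbp5 from 6.84 to -0.35, Wfdc2 from 4.50 to -0.62 and Ccl17 from -4.94 to 3.73 on day 7. Atp6v0d2 went from -3.69 to 0.15, Spp1 from -2.26 to 3.80 and Sparc from -1.13 to 0.19 on day 7, and the Lyve1-type list from 2.03 to 1.17 between mesenchyme and lung. The MHC class II list went from -1.49 to -0.18, Stab1 from 1.41 to -0.27, Lpl from 1.53 to -0.77 and Mertk from 1.32 to -0.52 between mesenchyme and lung. The Lyve1-type list went from -2.98 to -2.41, the MHC class II list from 1.58 to 1.30 and Ltf from -6.50 to 0.41 between epithelium and mesenchyme, and the pool share from 43.3% to 39.7% on day 1. In thinned cells, the classical monocyte list went from 3.52 to 4.18 and the alternative activation list from -0.013 to -0.10 on day 1, the alternative activation list from -0.0067 to -0.16 on day 4, and the classical monocyte list from -0.17 to -0.88 on day 7. Spp1 went from -2.26 to 0.18 on day 7, and the Lyve1-type list from 2.03 to 1.04, the MHC class II list from -1.49 to -1.72 and Lpl from 1.53 to -1.87 between mesenchyme and lung. Mertk went from 1.32 to -2.14 between mesenchyme and lung, and the MHC class II list from 1.58 to 1.65 and Scgb3a1 from -1.98 to 0.33 between epithelium and mesenchyme. With the mean of cells, the alternative activation list went from -0.013 to -0.13 on day 1, the alternative activation list from -0.0067 to -0.10 on day 4, and the classical monocyte list from -0.17 to -1.19 on day 7. The alternative activation list went from -0.11 to -0.21 and Spp1 from -2.26 to 0.12 on day 7, and Scgb3a1 from -1.98 to 0.0012 between epithelium and mesenchyme. Scaled by the median of ratios, the MHC class II list went from 1.58 to 1.75 between epithelium and mesenchyme. In macrophage-like cells alone, the classical monocyte list went from 3.52 to 4.83, the alternative activation list from -0.013 to 0.24, Acp5 from -3.48 to 2.20 and Cd163 from -1.01 to 0.10 on day 1. The classical monocyte list went from -0.12 to 0.38, Acp5 from -4.82 to 1.26 and Atp6v0d2 from -2.91 to 0.93 on day 4, and the classical monocyte list from -0.17 to 0.86 on day 7. Acp5 went from -5.98 to 0.15, Atp6v0d2 from -3.69 to 0.16 and Spp1 from -2.26 to 3.28 on day 7.

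Without cells rich in epithelial RNA, Ccl22 went from -3.66 to 1.53 and Ccl17 from -3.20 to 3.71 on day 4, and the classical monocyte list from -0.17 to -0.32 and Lypd2 from 5.17 to -0.062 on day 7. Ccl17 went from -4.94 to 1.98 and Ccl22 from -4.94 to 0.16 on day 7, and Scgb3a1 from -1.98 to 0.050 between epithelium and mesenchyme. With the cluster led by Retnla and Mmp12 added, the classical monocyte list went from 3.52 to 3.04 and the pool share from 43.3% to 45.8% on day 1, the pool share from 39.8% to 44.0% on day 4, and the pool share from 38.8% to 43.3% on day 7. Without the highest doublet scores, the MHC class II list went from 1.58 to 1.63 between epithelium and mesenchyme. Without the highest cell of each gene, the classical monocyte list went from 3.52 to 5.11, Ctsk from -7.15 to 1.15 and Acp5 from -3.48 to 2.64 on day 1, and the classical monocyte list from -0.12 to 0.031 on day 4. Acp5 went from -4.82 to 0.92, Atp6v0d2 from -2.91 to 0.38 and Sparc from -2.46 to 0.21 on day 4, and the classical monocyte list from -0.17 to -0.073 on day 7. Wfdc2 went from 4.50 to -0.0054, Lypd2 from 5.17 to -0.073, Acp5 from -5.98 to 0.074 and Ccl17 from -4.94 to 1.34 on day 7. Spp1 went from -2.26 to 2.91 and Sparc from -1.13 to 0.70 on day 7, and the classical monocyte list from -2.76 to 0.10 and the Lyve1-type list from 2.03 to 2.70 between mesenchyme and lung. The MHC class II list went from -1.49 to -0.98, Lpl from 1.53 to -0.28 and Mertk from 1.32 to -0.30 between mesenchyme and lung, and the lymphocyte and eosinophil chemokine list from -1.25 to 0.53 between epithelium and mesenchyme. Scgb3a1 went from -1.98 to 0.047 between epithelium and mesenchyme. Against lung alveolar macrophage-like cells, the Lyve1-type list went from 2.03 to 5.93, the MHC class II list from -1.49 to 3.49, the interferon response list from -1.26 to 2.20 and the fibroblast list from -3.60 to 0.30 between mesenchyme and lung. Cd74 went from -1.41 to 4.92, H2-Aa from -1.41 to 4.55, H2-Ab1 from -1.19 to 4.73 and H2-Eb1 from -1.38 to 4.88 between mesenchyme and lung. Ciita went from -3.05 to 2.43, Lpl from 1.53 to -4.40 and Mertk from 1.32 to -1.41 between mesenchyme and lung. Without the Lyve1 cluster, the classical monocyte list went from -2.76 to 0.22, the Lyve1-type list from 2.03 to 0.88 and the MHC class II list from -1.49 to -0.54 between mesenchyme and lung. The Lyve1-type list went from -2.98 to -1.96, the MHC class II list from 1.58 to 0.65 and Vsig4 from -2.98 to 1.29 between epithelium and mesenchyme. In whole-trachea cluster 0 alone, the classical monocyte list went from 3.52 to 0.70, the Lyve1-type list from -1.22 to 0.0017 and the inflammatory list from 1.94 to -0.28 on day 1. The alternative activation list went from -0.013 to 0.11 and the neutrophil list from 3.81 to -1.31 on day 1, and the classical monocyte list from -0.12 to 0.43 on day 4. The alternative activation list went from -0.0067 to -0.37 on day 4, and the classical monocyte list from -0.17 to -0.12 and the alternative activation list from -0.11 to -0.41 on day 7. In whole-trachea cluster 5 alone, the classical monocyte list went from 3.52 to 0.47, the Lyve1-type list from -1.22 to 0.072 and the alternative activation list from -0.013 to 0.34 on day 1, and the classical monocyte list from -0.12 to -0.48 on day 4. The alternative activation list went from -0.0067 to 0.19 and the neutrophil list from -1.11 to 0.52 on day 4, and the alternative activation list from -0.11 to -0.010 and the lymphocyte list from 1.30 to -1.49 on day 7. For cluster 0 against cluster 11, the Lyve1-type list went from -2.98 to -4.36 and the MHC class II list from 1.58 to 3.04 between epithelium and mesenchyme. For cluster 0 against cluster 15, the MHC class II list went from 1.58 to 0.75 between epithelium and mesenchyme. For cluster 11 against cluster 12, the Lyve1-type list went from 2.03 to 6.22, the MHC class II list from -1.49 to 2.92 and the growth factor list from -1.31 to 0.032 between mesenchyme and lung. The interferon response list went from -1.26 to 2.31, the proliferation list from -2.83 to 0.32 and the fibroblast list from -3.60 to 0.36 between mesenchyme and lung. For cluster 15 against cluster 12, the Lyve1-type list went from 2.03 to 2.80, the MHC class II list from -1.49 to 4.59 and the interferon response list from -1.26 to 1.54 between mesenchyme and lung. The proliferation list went from -2.83 to 0.41 and the fibroblast list from -3.60 to 0.079 between mesenchyme and lung.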

Other observations

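No tests chosen after the result was seen stand in this part, which gives values of cells that the comparisons did not use. Other immune classes of the whole trachea are given in the order no injury named, days 1, 4 and 7. Type 2 conventional dendritic cell-like cells made up 18.2%, 15.2%, 18.2% and 19.4%, mature dendritic cell-like cells 0%, 1.74%, 0.848% and 0.790%, type 2 innate lymphoid-like cells, a source of type 2 cytokines, 10.2%, 4.12%, 6.64% and 7.72%, and mast cell-like or basophil-like cells 2.5%, 0.900%, 1.70% and 1.34%. Lymphocyte-like cells made up 8.86%, 7.14%, 9.89% and 9.90%, and fibroblast-like cells, which a CD45 sort should leave out, 2.27%, 1.74%, 1.13% and 1.58%. On day 1 most type 2 conventional dendritic cell-like cells came from cluster 10, of whose 191 cells 169 were from that library.

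Cells with a UMI of Mki67 or Top2a, which dividing cells express, made up 14.8%, 14.4%, 11.7% and 11.7% of the pool, and 17.9%, 12.6%, 17.1% and 13.5% of lymphocyte-like cells, at median depths from 12330 to 14414 and from 6215 to 9287 UMIs. Thinned to 5000 UMIs, the shares were 5.23%, 5.64%, 6.69% and 5.12% of the pool and 13.5%, 6.59%, 14.4% and 10.6% of lymphocyte-like cells. Lymphocytes divide too, so their share is no background, and the whole-trachea cluster 9, led by Top2a and Mki67, stayed unnamed and outside the pool with 15, 27, 89 and 95 cells. Division of pool cells is therefore not read from these shares. Cells with a Lyve1, Folr2 or Cd163 UMI made up 78.2% of the pool on day 4 and 82.8% on day 7, against 11.4% and 16.6% of lymphocyte-like cells, and thinned 74.8% and 80.4% against 12% and 16.2%.

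Among the tissue libraries, macrophage-like cells made up 19.1% (14.9 to 23.8) of the epithelium, 54.9% (51.2 to 58.6) of the mesenchyme and 1.56% (0.629 to 3.19) of the lung library, each set by its own sort. The epithelium library held 79 endothelial-like, 51 fibroblast-like, 41 natural killer cell-like and 29 B cell-like cells among 325, and 3 that were epithelial-like. In the same order of the first 4 classes, the lung library held 48, 23, 10 and 38 cells and the mesenchyme library 3, 19, 0 and 0. The epithelial-like cluster was led by Ager, Igfbp2, Cldn18 and Aqp5, and held 5 cells of the lung and 0 of the mesenchyme. The mesenchyme library held 198 type 2 conventional dendritic cell-like cells, and the lung library 55 classical monocyte-like and 210 alveolar macrophage-like cells. Unnamed clusters held 17, 59 and 3 cells of epithelium, mesenchyme and lung. A Lyve1, Folr2 or Cd163 UMI was found in 14.5% of the 62 macrophage-like cells of the epithelium, at a median of 2760 UMIs, against 1.30% of its lymphocyte-like cells at 1785, and in 89.7% of the 396 macrophage-like cells of the mesenchyme at 4554. Thinned to 1500 UMIs, with 14 and 0 macrophage-like cells left out, the shares were 12.5% and 80.05%. Scgb1a1 UMIs were found in 93.5% of macrophage-like and 96.1% of lymphocyte-like cells of the epithelium, so this secretory cell transcript was background there.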
